A study of Mus musculus with 6 samples.

How the data were processed

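RNA was sequenced from the epidermis of newborn mice, with 3 libraries labelled Paxbp1 knockout and 3 labelled wild type. Per the labels' protocols, subcutaneous fat and dermis were removed, the tissue was kept in Dispase II overnight, the remaining dermis was peeled off and total RNA was extracted from the epidermis. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mouse build mm10. The alignment and counting parameters, the strand setting and the annotation release are not given in the sources used here.

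The authors deposited a table of whole-number read counts per gene and a table of FPKM (fragments scaled by gene length and library size) for the same 6 libraries and 54532 genes, each with Ensembl identifiers, symbols, positions and gene types. The deposited counts were used as they stand for the main comparison, and the deposited FPKM values only for an alternative test. No entry was blank or a summary line. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical family members can be split between them. The labels do not say whether each library came from 1 animal or from separate litters, so p-values measure the spread between these libraries.

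Totals ran from 16315317 to 17816327 counts per library. edgeR 4.0.16 in R 4.3.3 was used with TMM factors, its expression filter (minimum count 10, minimum total 15), robust dispersion estimates and the quasi-likelihood test, with genotype as the only term. The filter kept 16471 genes, which held at least 99.7% of the counts of every library. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Levels are CPM values as edgeR's cpm function gives them with the TMM factors, reported as mean ± SD over 3 libraries, and log2 fold changes are knockout minus wild type ± SE. The SE was derived as the absolute log2 fold change over the square root of the quasi-likelihood F. The interval of the Paxbp1 fold and the weights of Cochran's Q rest on it. A fold against a group with no count was computed against a floor of 3 counts over the group, and a gene with 1 to 3 counts in a group has its ratio with an exact 95% counting interval. These intervals and floors cover counting error only.

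The design, the alternatives, 35 gene lists with 1128 genes and the rule for named genes were fixed before the data were examined. The rule took Paxbp1, the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 5 CPM, non-overlapping groups and a symbol that is not a clone name, and from each list the 2 members with the smallest adjusted p in its majority direction and 1 in the other. Since more than 60 genes resulted, lists of other cell types gave their most abundant member only. Means for the rule were taken on CPM without TMM factors. With these factors the most abundant Merkel cell gene was Krt8 (12.3 CPM) and not Chga (11.8 CPM), so both are given, and the other 10 lists gave the same gene. Any other gene named in the text is a list member chosen after its values were seen. Some genes that the rule names are not reported here. Krt85 and Ahsp matched no gene of the count table. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list's own genes move one way without comparing them with others. P-values were adjusted over the 35 lists.

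Alternatives were RLE, upper-quartile and library-size scaling, no filter and a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the test without robust estimation, a replicate block, each library left out in turn, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), protein-coding genes only, sex as a covariate, and lists without shared members. A fit without both libraries numbered 1 was added after seeing the data, since these had the most genes with a count (24236 and 24380, against 22059 to 22556 in the others) and the highest Paxbp1 of their group.

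The replicate numbers in the titles were checked for pairing. Deviations from the group means correlated at 0.23, 0.34 and 0.18 across genes for libraries with the same number, and at -0.32 to 0.07 for other pairs. With 3 libraries per group few matchings are possible, and deviations from a group mean depend on each other. These values therefore cannot settle a pairing, and the labels do not say what a number marks. The main test used genotype only, with the replicate block as an alternative. Libraries of a group differed by far more than sampling noise (chi-square over its degrees of freedom 32.9 to 90.3), so none was counted as a duplicate. The test was run on simulated counts with the real means, library sizes and dispersions in which 200 genes were changed. For knockout against wild type over 16064 genes it recovered 4.17% of genes changed 1.5-fold, 19.1% at 2-fold, 90.0% at 4-fold and 95.7% at 8-fold, and called 7 of 15872 unchanged genes. Figures were drawn with matplotlib 3.10.9.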

Results

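Gene expression was measured by RNA-seq in newborn mouse epidermis, the stratified epithelium of the skin, to ask how Paxbp1 acts in this tissue. Paxbp1 encodes a protein that binds the Pax3 and Pax7 transcription factors. There were 3 libraries labelled Paxbp1 knockout and 3 labelled wild type, with totals between 16315317 and 17816327 counts. On log2 CPM, libraries of a group correlated at 0.978 to 0.980 in the wild type and 0.957 to 0.969 in the knockout, and libraries of different groups at 0.660 to 0.725. The first principal component held 88.3% of the variance. The 10 most counted genes took 11.7% to 16.1% of the counts in the wild type libraries and 4.42% to 5.74% in the libraries labelled knockout. From Xist and Y-linked genes, 2 wild type libraries read as male and 1 as female, and 1 library labelled knockout as male and 2 as female.

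Paxbp1 (ENSMUSG00000022974, chromosome 16, 91014037 to 91044543, minus strand, mm10) was not lower in the libraries labelled knockout. Its counts were 2007, 1159 and 1467 in wild type replicates 1 to 3 and 2370, 1127 and 1125 in the libraries labelled knockout. The level was 86.1 ± 20.6 CPM in the wild type and 92.5 ± 36.2 CPM in the knockout (SD, n = 3 each; log2 fold change 0.10 ± 0.29, edgeR adjusted p = 0.783). The 95% interval of the fold ran from 0.690 to 1.67. The log2 fold change was -0.25 without knockout replicate 1 and -0.0275 without wild type replicate 2, and neither was called. The labels do not state which part of the gene was deleted, and a count over the whole gene cannot show the loss of a few exons. The gene total therefore does not check the genotype labels, and every direction given here is that of the libraries labelled knockout against those labelled wild type.

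**Figure D1:**
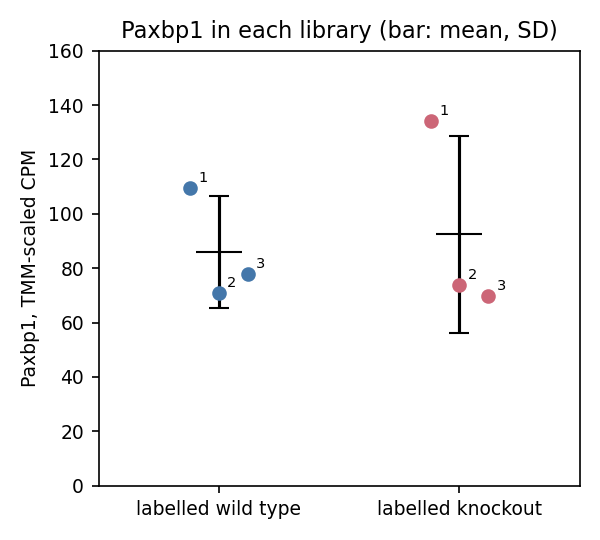
Paxbp1 level in TMM-scaled CPM (vertical axis) in each library, numbered by replicate, with the mean and SD of each group. The libraries labelled wild type lie between 70.8 and 110 CPM and those labelled knockout between 69.7 and 134 CPM.

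Of 16471 genes tested, 4721 were higher and 4139 lower in the libraries labelled knockout (edgeR adjusted p under 0.05), of which 3878 and 3216 changed at least 2-fold. The 3 knockout libraries lay on one side of the 3 wild type libraries for 62.3% of the genes, where chance gives 10%. Ccl8, a monocyte chemokine, went from no count to 1261 ± 515 CPM (at least 22070-fold higher). Saa3, an acute-phase protein, went from no count to 1148 ± 555 CPM (at least 20000-fold higher). Ccl7, Ccl24, Chil3 and the coagulation factor gene F10 also had no wild type count, with rises of at least 6842-, 4546-, 5560- and 5039-fold. The scavenger receptor gene Cd163 had 1 count over the wild type libraries and 3129 ± 1176 CPM in the knockout (ratio 165700, counting interval 29740 to 6545000). Spp1, which encodes osteopontin, had 2 wild type counts and 2889 ± 947 CPM in the knockout (ratio 76140, 21080 to 628700).

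The 8 largest falls included genes with almost no count left. Skint9 (chromosome 4, 112385969 to 112433985), of a family of keratinocyte membrane proteins, had 8107 wild type counts and none in the knockout (at least 2479-fold lower). Oas1f had 3571 and none (at least 1092-fold lower). Adh6b kept 2 counts against 2520 (ratio 0.000865, 0.000105 to 0.00313) and Scube1 1 against 1294 (ratio 0.000842, 2.13e-05 to 0.00470). Atp6v1b1, a proton pump subunit, fell from 123 ± 19.1 to 0.0755 ± 0.131 CPM, and Ano7 from 115 ± 35.1 to 0.179 ± 0.171 CPM. Gadl1 fell by 9.35 on the log2 scale. Shh, which encodes the hair placode signal Sonic hedgehog, fell from 78.6 ± 7.30 to 0.181 ± 0.186 CPM (log2 fold change -8.69 ± 0.48, edgeR adjusted p = 2.44e-07). Skint and Oas1 genes have close relatives, and reads could be split between them.

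Camera with the preset correlation passed 24 of the 35 gene lists. It also passed 14 to 22 lists when the 6 libraries were split in the 9 other ways, and no list passed with an estimated correlation. That setting takes its degrees of freedom from the 6 libraries and loses calls even where the correlation hardly differs. For the nerve list it was estimated at 0.0175, near the preset 0.01, yet the camera p went from 0.00506 to 0.0530. A call lost there therefore does not by itself argue against a list. For other lists the estimate lay far above the preset, at 0.636 for spinous, 0.619 for granular, 0.561 for macrophage and 0.551 for fibroblast genes. There the preset p is too small for genes that vary together, and the loss bears on it. Each list is therefore given with its count of called members. Over all genes tested 28.7% were higher and 25.1% lower, and a list with shares near these is not set apart by its count. A p of the preset test alone does not set the groups apart from other splits. These splits cannot show how many lists pass without a group difference, since each keeps part of it. Library-size and upper-quartile scaling moved the median of all genes from -0.029 to -0.18 and -0.22, and a list median of that size depends on the scaling.

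Most genes of the keratinocyte layers were lower. Of 25 basal layer genes 18 were lower and 4 higher (18 and 5 adjusted over the list alone). The basal median log2 fold change was -2.37 (camera adjusted p = 0.00124, and adjusted p = 0.343 with an estimated correlation). Of 31 spinous layer genes 26 were lower and 1 higher (27 and 1 adjusted over the list alone). The spinous median was -2.25 (camera adjusted p = 4.43e-07, and adjusted p = 0.479 with an estimated correlation). Of 47 genes of the granular layer and cornified envelope 30 were lower and 7 higher (31 and 8 adjusted over the list alone). The granular median was -1.72 (camera adjusted p = 0.00184, adjusted p = 0.643 with an estimated correlation, and fry adjusted p = 0.113). In the same libraries 27 of 28 fibroblast and 24 of 25 macrophage genes were higher.

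The size of the fall differed between keratinocyte genes. The basal keratin Krt15 went from 3021 ± 305 to 41.0 ± 25.2 CPM, and Krt14 from 5578 ± 642 to 2103 ± 1080 CPM (edgeR adjusted p = 0.0206). Krt14 was not called without wild type replicate 2 (adjusted p = 0.0559) or 3 (adjusted p = 0.0621). The suprabasal keratins Krt1 (30670 ± 8753 to 2721 ± 1256 CPM) and Krt10 (29010 ± 11850 to 2136 ± 1005 CPM) and the cornified envelope gene Lor (20440 ± 9276 to 616 ± 208 CPM) fell by 3.49, 3.76 and 5.05 on the log2 scale. The members with the smallest adjusted p were Sox6 and Sostdc1 in the basal list, Krt77 and Skint3 in the spinous list, and the histidine-degrading enzyme gene Hal and Lce1m in the granular list. Their log2 fold changes were -4.11, -3.95, -5.67, -2.56, -6.46 and -6.93. Against these lists, Igfbp3 rose (3.50 ± 0.31), as did the cornified envelope gene Sprr3, which had 2 wild type counts (ratio 811, 224 to 6703). The arginase gene Arg1, a member of the granular list that macrophages also express, rose from 13.2 ± 8.06 to 4306 ± 1276 CPM.

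**Figure D2:**
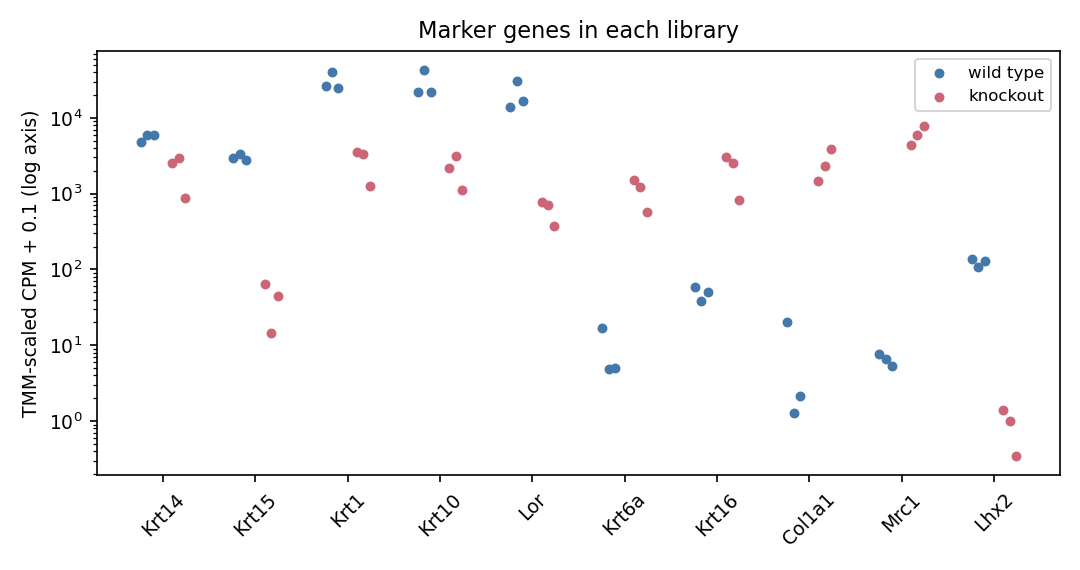
TMM-scaled CPM plus 0.1 (log axis) of 10 genes in each library labelled wild type (blue) or knockout (red), 1 point per library in the order of the replicate numbers. The groups do not overlap for any of these genes. Krt14 fell by 1.41 and Krt15 by 6.20 on the log2 scale, and Krt6a, Krt16, Col1a1 and Mrc1 rose.

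Genes of barrier lipids were lower for 18 of 37 members and higher for 5 (19 and 5 adjusted over the list alone). The barrier lipid median was -1.15 (camera adjusted p = 0.00754, adjusted p = 0.640 with an estimated correlation, and fry adjusted p = 0.0621). Pla2g2f, an epidermal phospholipase gene, fell from 619 ± 110 to 29.0 ± 12.9 CPM and the fatty acid elongase gene Elovl6 from 62.2 ± 8.50 to 13.5 ± 2.48 CPM. The glucosylceramide synthase gene Ugcg rose from 61.3 ± 12.4 to 272 ± 22.1 CPM. Of 21 tight junction genes 12 were lower and 2 higher (the same numbers adjusted over the list alone). The tight junction median was -1.09 (camera adjusted p = 0.00770, and adjusted p = 0.551 with an estimated correlation), and -1.64 without knockout replicate 1. Tjp3 (-3.19 ± 0.24) and Cldn23 (-4.38 ± 0.42) fell and Cldn3 rose (2.28 ± 0.67). Cldn3 was not called without both libraries numbered 1 (adjusted p = 0.0621), where no tight junction gene was higher, and 1 was without any 1 wild type library or knockout replicate 1. Of 25 cholesterol synthesis genes 10 were lower and 5 higher (the same numbers adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.270, fry adjusted p = 0.0193). Hsd17b7 (-1.78 ± 0.21) and Dhcr7 (-1.82 ± 0.21) fell and Insig1 rose (1.44 ± 0.26). Beside these 3 lists, 27 of 28 fibroblast, 24 of 25 macrophage and 10 of 11 neutrophil genes were higher in the same libraries.

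Stress keratins and alarmins, which keratinocytes make in wounded or inflamed skin, were higher for 37 of 43 members and lower for 2 (the same numbers adjusted over the list alone). The stress keratin median was 4.82 (camera adjusted p = 1.19e-11, and adjusted p = 0.301 with an estimated correlation). The wound keratin Krt6a went from 8.85 ± 6.93 to 1106 ± 479 CPM and Krt16 from 48.8 ± 10.3 to 2130 ± 1153 CPM. The calprotectin subunit genes S100a8 and S100a9 went from 0.152 ± 0.133 to 2158 ± 1082 CPM and from 0.197 ± 0.216 to 2637 ± 1265 CPM. Neutrophils also make both, and 10 of 11 neutrophil genes were higher in these libraries. Plaur (7.23 ± 0.32) and the protease inhibitor gene Slpi (9.27 ± 0.48) had the smallest adjusted p, and the cystatin gene Stfa3 fell (-2.04 ± 0.46). On leaving out wild type replicate 2 or 3, or knockout replicate 3, 1 member of this list was lower.

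Of 27 targets and components of the Notch, Wnt and Hedgehog pathways 19 were lower and 5 higher (20 and 5 adjusted over the list alone). The pathway median was -2.95 (camera adjusted p = 7.13e-05, and adjusted p = 0.263 with an estimated correlation). The Hedgehog receptor gene Ptch1 (508 ± 106 to 19.0 ± 8.98 CPM) and the effector gene Gli1 (223 ± 63.5 to 3.95 ± 2.66 CPM) fell with Shh. The YAP target Cyr61 rose (3.57 ± 0.26). Of 21 hair follicle genes tested 13 were lower and 2 higher (the same numbers adjusted over the list alone). The hair follicle median was -2.47 (camera adjusted p = 0.00232, and adjusted p = 0.512 with an estimated correlation). The transcription factor genes Lhx2 (126 ± 15.6 to 0.822 ± 0.534 CPM) and Sox21 (75.6 ± 1.02 to 1.27 ± 0.730 CPM) fell and Trps1 rose (3.87 ± 0.36). Fibroblast and macrophage genes were higher in the same libraries (27 of 28 and 24 of 25).

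Most cell cycle genes were lower. Of 58 mitosis genes 56 were lower and 1 higher (the same numbers adjusted over the list alone). The mitosis median was -1.48 (camera adjusted p = 1.95e-12, and adjusted p = 0.263 with an estimated correlation). Cenpf (-2.63 ± 0.25) and the condensin subunit gene Ncapd2 (-2.01 ± 0.20) fell, and Pttg1, which encodes securin, rose (1.13 ± 0.22). Of 44 DNA replication genes 32 were lower and 1 higher (33 and 1 adjusted over the list alone). The replication median was -1.13 (camera adjusted p = 8.82e-07, and adjusted p = 0.344 with an estimated correlation). Mcm5 (-1.89 ± 0.21) and Prim1 (-1.79 ± 0.20) fell and E2f1 rose (0.67 ± 0.20). E2f1 was not called without wild type replicate 2 (adjusted p = 0.0917), nor with library-size (0.0598) or upper-quartile (0.0576) scaling. Of 48 DNA damage response and repair genes 32 were lower and 2 higher (the same numbers adjusted over the list alone). The repair median was -1.03 (camera adjusted p = 2.37e-06, and adjusted p = 0.263 with an estimated correlation). Xrcc5 fell from 32.4 ± 2.52 to 7.80 ± 1.13 CPM and Ercc1 rose (0.95 ± 0.24). Without wild type replicate 1 or 2, or both libraries numbered 1, 1 repair gene was higher. In these libraries keratinocyte layer genes were mostly lower, and 27 of 28 fibroblast, 24 of 25 macrophage and 10 of 11 neutrophil genes were higher.

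Of 41 p53 target genes 18 were higher and 7 lower (18 and 8 adjusted over the list alone). The p53 median was 0.56 (camera adjusted p = 0.168, fry adjusted p = 0.00957). The death receptor gene Fas (3.58 ± 0.31), Apaf1 (2.26 ± 0.25) and Mdm2 (1.81 ± 0.25) rose and Trp73 fell (-3.16 ± 0.55). Without wild type replicate 2 or 3, or knockout replicate 3, 4 p53 targets were lower. Over all alternatives the lower p53 targets ranged from 4 to 11 and the higher from 15 to 20. The cell cycle inhibitor gene Cdkn1a had 287 ± 37.8 CPM in the wild type and 266 ± 23.2 CPM in the knockout (edgeR adjusted p = 0.707). Of 34 apoptosis regulators 21 were higher and 3 lower (the same numbers adjusted over the list alone). The apoptosis median was 0.99 (camera adjusted p = 0.00224, and adjusted p = 0.478 with an estimated correlation). The necroptosis kinase gene Ripk3 rose (3.25 ± 0.23), its substrate Mlkl had 3 wild type counts (ratio 185, 62.9 to 900), and Bcl2 fell (-1.84 ± 0.28). Leukocytes also express Fas, Ripk3 and Mlkl, and macrophage (24 of 25) and neutrophil (10 of 11) genes were higher in the same libraries.

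Of 39 genes of the integrated stress and unfolded protein responses 21 were higher and 8 lower (22 and 8 adjusted over the list alone). The stress response median was 0.78 (camera adjusted p = 0.0468, and adjusted p = 0.639 with an estimated correlation). Atf3 (3.46 ± 0.23) and Edem1 (2.90 ± 0.25) rose and the serine synthesis gene Phgdh fell (-3.39 ± 0.33). This list was not called without wild type replicate 1 (camera adjusted p = 0.103), wild type replicate 3 (0.0719) or knockout replicate 2 (0.0616), and its adjusted p ranged from 0.0220 to 0.131 over the alternatives. Of 45 NRF2 and antioxidant genes 22 were higher and 8 lower (23 and 10 adjusted over the list alone). The NRF2 median was 0.63 (camera adjusted p = 0.104, fry adjusted p = 0.0113), and the list was called without knockout replicate 1 (camera adjusted p = 0.0461). Cyba, which encodes a subunit of the phagocyte NADPH oxidase (4.61 ± 0.33), and the glutathione reductase gene Gsr (2.80 ± 0.23) rose and Gsta2 fell (-4.73 ± 0.32). Phagocyte genes were higher in the same libraries (24 of 25 in the macrophage and 10 of 11 in the neutrophil list).

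Few members were called in the lists of RNA processing and energy metabolism. Of 78 spliceosome genes 10 were lower and 4 higher (2 and 1 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.175). Prpf19 (-1.06 ± 0.20) and Snrnp25 (-1.30 ± 0.32) fell and Dhx38 rose (0.88 ± 0.21). Of 46 ribosome biogenesis genes 10 were lower and 1 higher (0 and 1 adjusted over the list alone). The ribosome biogenesis median was -0.33 (camera adjusted p = 0.0136, adjusted p = 0.686 with an estimated correlation, and fry adjusted p = 0.139). Nop58 (-0.91 ± 0.23) and Dkc1 (-0.98 ± 0.28) fell and Heatr1 rose (2.08 ± 0.24). Of 55 oxidative phosphorylation genes 7 were lower and 5 higher (1 and 2 adjusted over the list alone), with a median of -0.087 (camera adjusted p = 0.443). Atp5g1 (-1.08 ± 0.24) and Cyc1 (-0.62 ± 0.19) fell and Ndufa1 rose (1.69 ± 0.28).

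These member counts depended on single libraries and on the fit. With the replicate block 17 were lower and 8 higher for the spliceosome, 16 and 1 for ribosome biogenesis, and 12 and 7 for oxidative phosphorylation. Without wild type replicate 3 the lower members numbered 3, 2 and 1, and neither Cyc1 (edgeR adjusted p = 0.0802) nor Dkc1 (0.0528) was called. Lower members of the 3 lists numbered 5, 5 and 5 without wild type replicate 1, 6, 4 and 2 without wild type replicate 2, and 6, 2 and 4 without knockout replicate 3. Oxidative phosphorylation had 4 lower without knockout replicate 1 and 15 without knockout replicate 2. Higher spliceosome members numbered 2 without any 1 wild type library and 7 without knockout replicate 1. Higher oxidative phosphorylation members numbered 2 without wild type replicate 1 or knockout replicate 2 and 3 without wild type replicate 3. Over all alternatives the lower members ranged from 3 to 20, from 2 to 18 and from 1 to 15. Without knockout replicate 2 the spliceosome (camera adjusted p = 0.0486) and oxidative phosphorylation (0.0385) lists were called, with medians of -0.24 and -0.36. Without knockout replicate 1 the oxidative phosphorylation median was 0.10. The ribosome biogenesis list was not called without knockout replicate 3 (camera adjusted p = 0.120, median -0.21) or with DESeq2 (0.0902). Its median was -0.52 with upper-quartile factors and -0.54 without both libraries numbered 1.

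Of 12 mitochondrially encoded transcripts 3 were higher and none lower (none adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.545). They included mt-Co2 (0.98 ± 0.33) and mt-Nd3 (0.70 ± 0.26). With upper-quartile factors none was higher and 1 lower, and with library size only none was called. Neither mt-Co2 (edgeR adjusted p = 0.0676 and 0.0860) nor mt-Nd3 (0.107 and 0.101) was called under these scalings. With the replicate block 1 member was higher, and mt-Co2 was not called (adjusted p = 0.0577). No member was higher without wild type replicate 1 or 2 or knockout replicate 2, and 1 was higher and 1 lower without wild type replicate 3. Without wild type replicate 1 neither mt-Co2 (edgeR adjusted p = 0.0931) nor mt-Nd3 (0.0667) was called, and likewise without wild type replicate 2 (0.0938 and 0.144) or knockout replicate 2 (0.0549 and 0.138). The first was not called without knockout replicate 1 (0.0839), nor the second without wild type replicate 3 (0.0658) or knockout replicate 3 (0.0616). Without both libraries numbered 1, mt-Co2 rose by 0.53 and was not called (edgeR adjusted p = 0.248), nor was it on log2(FPKM + 1) (limma-trend adjusted p = 0.0516). Of 12 replication-dependent histone genes tested 3 were higher and 2 lower (the same numbers adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.610). Hist1h2bc (1.43 ± 0.29) and Hist1h2be (1.44 ± 0.42) rose and Hist1h1d fell (-1.55 ± 0.50). Without wild type replicate 3 neither Hist1h2be (edgeR adjusted p = 0.0642) nor Hist1h1d (0.0621) was called, and Hist1h1d was not called without wild type replicate 1 (0.115) or knockout replicate 3 (0.0735). Hist1h1d also lost its call without a filter (edgeR adjusted p = 0.0527), with sex as a covariate (0.0620) and without both libraries numbered 1 (0.0999). On log2(FPKM + 1) its change was -0.18 (limma-trend adjusted p = 0.0678). Of the histone genes 1 was higher without wild type replicate 3, and from 1 to 4 were with each library left out in turn. None was lower without wild type replicate 1 or 3 or both libraries numbered 1. On leaving out wild type replicate 2, knockout replicate 2 or 3, 1 was lower.

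Interferon and cytokine genes were higher. Of 42 interferon-stimulated genes 40 were higher and none lower (41 higher adjusted over the list alone). The interferon median was 4.12 (camera adjusted p = 2.77e-16, and adjusted p = 0.263 with an estimated correlation). The nucleic acid sensor gene Zbp1 went from 0.861 ± 0.227 to 45.2 ± 6.18 CPM, and Ifit1 rose by 7.10 ± 0.38 on the log2 scale. Of 33 cytokine and chemokine genes 26 were higher and 4 lower (the same numbers adjusted over the list alone). The cytokine median was 5.50, and 5.36 with 6 members at their bound (camera adjusted p = 3.96e-08, and adjusted p = 0.263 with an estimated correlation). The monocyte chemokine gene Ccl2 had 2 wild type counts and 282 ± 47.5 CPM in the knockout (ratio 7477, 2070 to 61750). Osm went from 0.0948 ± 0.0368 to 66.3 ± 8.59 CPM, and Il34, which sustains Langerhans cells, fell from 55.4 ± 14.9 to 2.42 ± 1.02 CPM. Leukocytes express many of these genes, and macrophage and neutrophil genes were higher in the same libraries.

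Langerhans cell and macrophage genes were higher for 24 of 25 members and lower for 1 (the same numbers adjusted over the list alone). The macrophage median was 4.60 (camera adjusted p = 8.21e-12, and adjusted p = 0.301 with an estimated correlation). The mannose receptor gene Mrc1 went from 6.44 ± 1.19 to 6063 ± 1663 CPM. Cx3cr1 fell from 21.2 ± 3.69 to 4.25 ± 1.48 CPM, and the Langerhans cell gene Cd207 had too few counts to be tested. Of 15 neutrophil genes 11 were tested, and of these 10 were higher and none lower (the same numbers adjusted over the list alone). Ly6g, Camp, Elane and Mpo had too few counts to be tested. Retnlg, Chil3 and Lrg1 had no wild type count, passed the filter through the knockout alone and could only be higher. The neutrophil median was 8.58, also with 3 members at their bound (camera adjusted p = 4.43e-07, and adjusted p = 0.263 with an estimated correlation). Csf3r went from 1.75 ± 0.471 to 675 ± 115 CPM.

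Of 28 dermal fibroblast genes 27 were higher and none lower (28 higher adjusted over the list alone). The fibroblast median was 6.30 (camera adjusted p = 1.19e-11, and adjusted p = 0.313 with an estimated correlation). Vim, which macrophages also express, went from 171 ± 22.3 to 5041 ± 1412 CPM and the collagen gene Col1a1 from 7.83 ± 10.8 to 2548 ± 1226 CPM. All 9 red blood cell genes tested were higher (9 adjusted over the list alone). The red blood cell median was 7.73, and 6.18 with 1 member at its bound (camera adjusted p = 1.04e-05, and adjusted p = 0.263 with an estimated correlation). The globin gene Hba-a1 went from 3.27 ± 1.24 to 728 ± 254 CPM.

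Endothelial genes were higher for 9 of 12 tested and lower for none (10 and 1 adjusted over the list alone, and 10 and 1 with the replicate block). Without wild type replicate 2, knockout replicate 1 or both libraries numbered 1, 1 endothelial gene was lower. The endothelial median was 4.19 (camera adjusted p = 0.00147, and adjusted p = 0.301 with an estimated correlation). Pecam1, which leukocytes also express, went from 1.20 ± 0.403 to 251 ± 84.1 CPM. The endothelial cadherin gene Cdh5 had 1 wild type count and 7.153 ± 2.905 CPM in the knockout (ratio 385, 68.6 to 15240). Of the 19 members listed, 4 reached 10 CPM in the knockout and 0 in the wild type. Those besides Pecam1 were Flt1 (38.6 CPM), Eng (19.9 CPM) and Vwf (13.0 CPM). All 5 adipocyte genes tested were higher (5 adjusted over the list alone). The adipocyte median was 3.28 (camera adjusted p = 0.00756, and adjusted p = 0.301 with an estimated correlation). Fabp4, which macrophages also express, went from 17.9 ± 11.7 to 353 ± 157 CPM, and Adipoq, with a mean of 0.680 CPM in the knockout, was too low to be tested. Of 27 skeletal muscle genes 15 were tested, and of these 8 were higher and 1 lower (8 and 2 adjusted over the list alone, and 9 and 2 with the replicate block). The muscle median was 2.97 (camera adjusted p = 0.0232, and adjusted p = 0.401 with an estimated correlation). No member reached 10 CPM in the knockout. Pax3, with the highest mean over both groups, fell from 9.61 ± 2.36 to 3.01 ± 0.289 CPM. Des, with the highest mean in the knockout, had 2 wild type counts, both in 1 library, and 7.83 ± 0.556 CPM in the knockout (ratio 210, 57.7 to 1739).

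Of muscle genes, 2 were lower without knockout replicate 1 or 3. The muscle list was not called with the stricter filter (camera adjusted p = 0.143), with DESeq2 (0.225) or on FPKM values (0.161 and 0.0523 with the larger and smaller pseudocount), and its adjusted p ranged from 0.00662 to 0.225 over the alternatives. Its median was 0.66 with that filter and 4.67 without both libraries numbered 1. Of 10 nerve and Schwann cell genes 7 were higher and none lower (the same numbers adjusted over the list alone, 7 and 1 with the replicate block, and 1 lower without knockout replicate 1 or both libraries numbered 1). The nerve median was 1.23 (camera adjusted p = 0.00844, and adjusted p = 0.263 with an estimated correlation). Mbp went from 21.5 ± 1.80 to 51.2 ± 10.3 CPM.

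The lists of melanocytes, Merkel cells and T cells were not called. Of 16 melanocyte genes 9 were lower and 4 higher (9 and 5 adjusted over the list alone), with a median of -0.98 (camera adjusted p = 0.141). The pigment enzyme gene Dct fell from 225 ± 37.1 to 69.5 ± 23.5 CPM. Of 10 Merkel cell genes 3 were lower and 2 higher (the same numbers adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.405, fry adjusted p = 0.0433). Without knockout replicate 1, 5 Merkel cell genes were lower and 1 higher, and 1 was also higher without wild type replicate 1 or 2, knockout replicate 2 or both libraries numbered 1. Krt8 had 10.6 ± 1.33 CPM in the wild type and 13.9 ± 1.84 CPM in the knockout (edgeR adjusted p = 0.185), and Chga fell from 23.3 ± 15.9 to 0.274 ± 0.254 CPM. T cell genes had a negative median (-0.73) and a positive mean (0.28), with 6 higher and 4 lower of 18 (6 and 5 adjusted over the list alone; camera adjusted p = 0.905, direction down, where fry's direction was up). The lower T cell genes numbered 1 without wild type replicate 1, 2 without knockout replicate 3 or both libraries numbered 1, and 7 without knockout replicate 2. Thy1, which fibroblasts also express, rose (2.73 ± 0.22) and the T cell receptor component gene Cd3e fell (-2.50 ± 0.75). Cd3e was not called without wild type replicate 1 (edgeR adjusted p = 0.0775) or with sex as a covariate (0.0751). None of the 5 sex-linked markers was called (none adjusted over the list alone), with a median of -0.52 (camera adjusted p = 0.610). Xist had 337 ± 583 CPM in the wild type and 575 ± 526 CPM in the knockout.

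**Figure D3:**
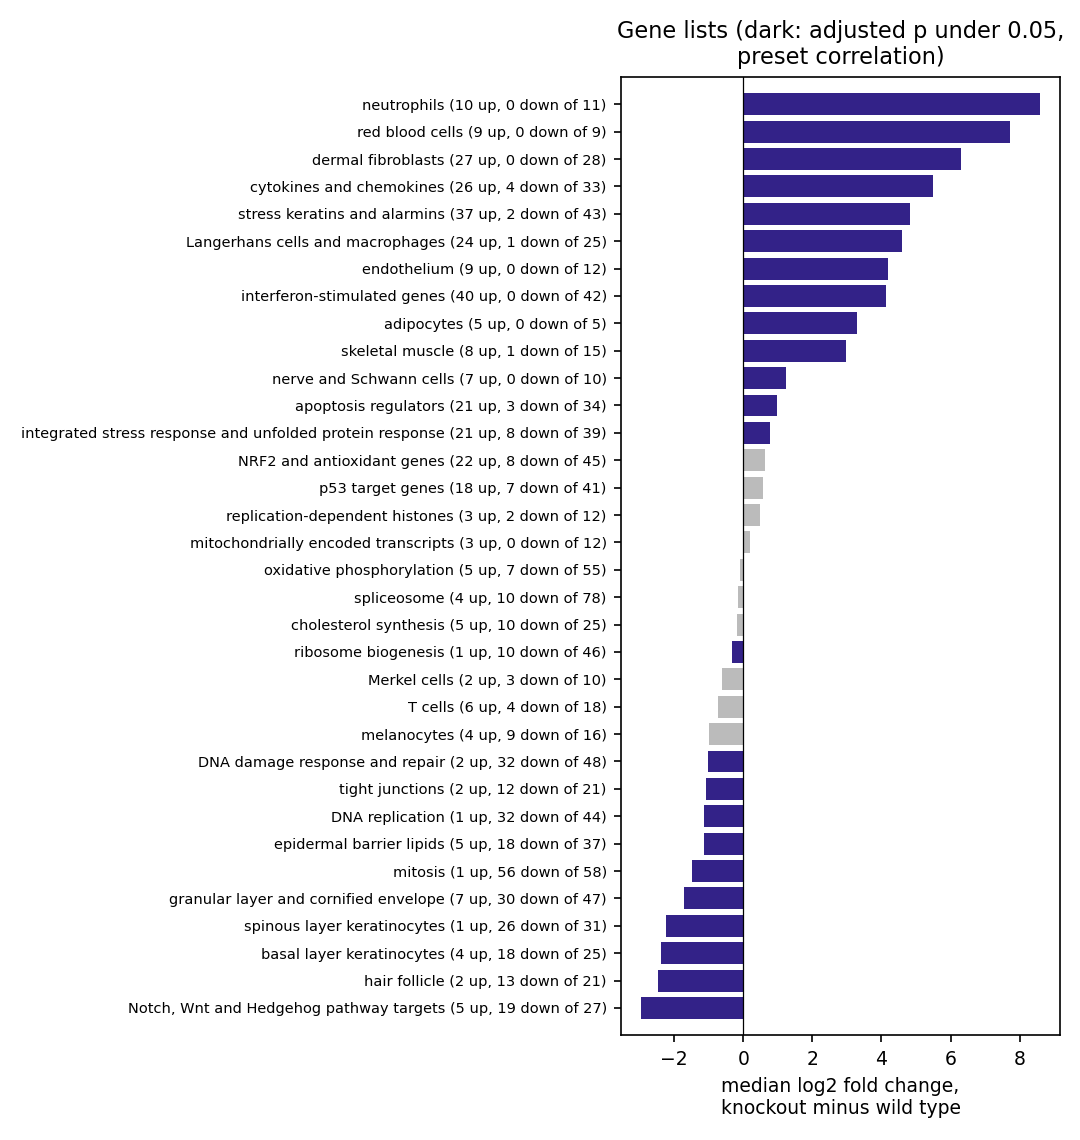
Median log2 fold change, knockout minus wild type (horizontal axis), of 34 gene lists, with the number of called members in each direction. Dark bars have a camera adjusted p under 0.05 at the preset correlation, which no list has with an estimated correlation. Medians run from -2.95 for the Notch, Wnt and Hedgehog list to 8.58 for the neutrophil list.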

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

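The fit without both libraries numbered 1 was chosen after seeing the data, and all other alternatives before. Numbers of called genes stayed within 1.5 times under every alternative, and no gene was called in opposite directions. Genes higher ranged from 4151 with upper-quartile factors to 5321 without a filter on low counts, and genes lower from 3388 without wild type replicate 3 to 5147 with upper-quartile factors. Without both libraries numbered 1, 4585 were higher and 3883 lower. The share of calls that were higher was 53.3% and ranged from 44.6% with upper-quartile factors to 56.3% without wild type replicate 1. DESeq2 gave no adjusted p for 7 genes. With the replicate block 5089 were higher and 4792 lower, and 8783 of 8860 genes kept call and direction. Beyond mt-Co2 it changed no call of a named gene or list. Member counts also moved outside the 7 lists given with the block. Lower members went from 32 to 38 for DNA damage response and repair and from 4 to 6 for T cells. Only 1 gene is in more than 1 list, so leaving out shared members tests little. Simulated 2-fold changes were recovered in 19.1% of cases by edgeR with 200 genes changed. That share does not carry over to the data, where 8860 genes were called and the threshold on the unadjusted p is less strict. Genes with too few counts for the filter, such as Cd207, were not tested, and nothing is said of their change.

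Paxbp1 changed sign with upper-quartile factors (-0.078), library size only (-0.024) and without both libraries numbered 1 (-0.066), and ranged from -0.25 to 0.33 with 1 library left out. It was called under none of them. Of 2459 values of named genes under the alternatives, 2418 kept direction and side of the threshold, 34 lost the call and 7 changed sign. Those 7 were 5 of Paxbp1 and 2 of Xist, also uncalled, at -0.63 with sex as a covariate and -0.55 without both libraries numbered 1.

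With an estimated correlation all 24 list calls were lost, at unchanged medians of -2.37 (basal), -2.25 (spinous), -1.72 (granular), -1.15 (barrier lipids), -1.09 (tight junctions), 4.82 (stress keratins), 0.99 (apoptosis), -1.13 (DNA replication), -1.48 (mitosis), -1.03 (DNA damage), 0.78 (integrated stress response), -0.33 (ribosome biogenesis), 4.12 (interferon), 5.50 (cytokines), -2.95 (Notch, Wnt and Hedgehog), -2.47 (hair follicle), 4.60 (macrophages), 8.58 (neutrophils), 6.30 (fibroblasts), 4.19 (endothelium), 3.28 (adipocytes), 2.97 (muscle), 7.73 (red blood cells) and 1.23 (nerve). That setting takes its degrees of freedom from the 6 libraries, so these losses alone do not argue against a list. Where the estimate lay far above 0.01, as for the spinous (0.636) and granular (0.619) lists, they bear on the preset p. Fry lost the granular, barrier lipid and ribosome biogenesis lists and called cholesterol synthesis (-0.19), p53 targets (0.56), NRF2 (0.63) and Merkel cells (-0.61). The integrated stress response list lost its call with the stricter filter (0.80), DESeq2 (0.81), protein-coding genes only (0.77) and without both libraries numbered 1 (0.82). The muscle list lost it with the stricter filter (0.66), DESeq2 (3.04), log2(FPKM + 1) (0.12) and log2(FPKM + 0.1) (0.88), and ribosome biogenesis with DESeq2 (-0.30). NRF2 was called without a filter (0.69). The sex-linked list, never called, changed sign with sex as a covariate (0.072) and without both libraries numbered 1 (0.15). With 1 library left out, medians ranged from 0.65 to 0.90 for the integrated stress response, 0.61 to 0.80 for NRF2, -0.24 to -0.11 for the spliceosome, -0.48 to -0.21 for ribosome biogenesis, -0.36 to 0.10 for oxidative phosphorylation and -12.26 to 0.070 for the sex-linked list. Medians that also moved by over 1.5 times, with no change of call, ranged from -1.64 to -0.86 for tight junctions, 0.35 to 0.74 for p53 targets, -0.29 to -0.11 for cholesterol synthesis, 0.0051 to 0.28 for mitochondrial transcripts, 0.19 to 0.51 for histones and -1.01 to -0.33 for Merkel cells. On log2(FPKM + 1), which understates changes of low genes, medians smaller by over 1.5 times were 2.32 for cytokines, -0.98 for hair follicle, 0.28 for p53 targets, -0.71 for tight junctions, 0.26 for histones, 3.26 for fibroblasts, 0.82 for endothelium, 1.93 for adipocytes, 2.74 for red blood cells, -0.64 for melanocytes, -0.12 for Merkel cells and -0.22 for T cells, besides muscle. The cause was not tested, except that some alternatives use fewer libraries or genes by construction.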

Other observations

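Gene families were grouped, after seeing the data, by the letters that open their symbols. A first grouping of 251 families by any opening letters had 20 higher and 8 lower. It was replaced, after this result, by prefixes of at least 3 letters, with 228 families of 8 to 100 tested protein-coding genes. Camera at the preset correlation then called 14 families higher and 7 lower. With an estimated correlation it called none (adjusted p = 0.996 for each family named here). That setting takes its degrees of freedom from the 6 libraries, so the loss alone does not argue against a family. The preset p is too small where members of a family correlate by more than 0.01. No family is set apart beyond the limits of the preset test.

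All 11 Skint genes tested were lower (median log2 fold change -5.31, camera adjusted p = 9.78e-06). Of these, 1 is in a list fixed earlier, and their reads can be shared. Wnt ligand genes were lower for 12 and higher for 3 of 15 (median -3.57, camera adjusted p = 0.00459), with 4 of them in fixed lists. Genes of the Hoxb cluster were lower for 7 and higher for 1 of 8 (median -3.59, camera adjusted p = 0.0190), and all 8 chromobox genes Cbx were lower (median -1.20, camera adjusted p = 0.00768). Matrix metalloproteinase genes were higher for 13 and lower for 1 of 17 (median 4.48, camera adjusted p = 8.93e-05), with 3 in fixed lists. Toll-like receptor genes were higher for 10 and lower for 1 of 11 (median 6.26, camera adjusted p = 0.000976), and sorting nexin genes for 21 and 3 of 29 (median 1.56, camera adjusted p = 0.00200). In the same libraries 24 of 25 macrophage, 10 of 11 neutrophil and 27 of 28 fibroblast genes were higher, and such cells express Toll-like receptor and metalloproteinase genes. These medians kept their sign under library-size, RLE and upper-quartile scaling.

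The tests from here on were chosen after the results they bear on had been seen, except those on other splits of the libraries. Among the 10 splits of the 6 libraries into 3 and 3, the real one called 8860 genes and the highest other 0 (edgeR, with 16 to 407 genes at an unadjusted p under 0.05 and up to 36 genes called by DESeq2), and 1 split, the real one, gave as many. The 3 other splits that part all 3 pairs of same-numbered libraries also called 0, and the remaining 6 part 1 pair. For lists at the preset correlation, the real split passed 24 and the highest other 22, or 21 among the splits that part all 3 pairs. These splits are too few for a share under 0.05. Each other split still sets 2 libraries of one group and 1 of the other against the rest, so a difference between the groups remains in it.

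The number of changed genes was set against the sex of the animals and against a few genes taking most of the counts. With sex as a covariate 90.2% of called genes kept call and direction. A few genes with a larger share in one group would move all other genes one way when only library size is used. Without the 10 most counted genes of each library, 4189 were then higher and 4704 lower, so 47.1% of the calls were in the less common direction. This test replaced one on genes changed at least 2-fold under other scalings, whose outcome was fixed since those shift all genes nearly alike. The values argue against either as the whole cause. Litter, age within the newborn period and strain background were not tested and stay open.

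Keratinocyte layer genes were lower while many genes of other cell types were higher. A lower share of keratinocyte RNA as the only cause would raise the 11 lists of other cell types alike, but 2 lists, melanocytes and Merkel cells, had more members lower than higher. The 159 genes also differed between lists (permutation p of the Kruskal-Wallis statistic 1e-05, the smallest that 100000 permutations can give). That p is over genes, which are not independent replicates. The list medians were known before this test was chosen, so its p adds nothing to them. Genes that passed the filter through the knockout alone also widen the spread. Dilution as the only cause of the lower genes would give the 74 lower layer genes 1 common fold, but Cochran's Q was 7.76 times its degrees of freedom. Genes that other cells also express could fall less, but over the 6 lower keratins alone, from Krt14 (-1.41) to Krt15 (-6.20), it was 12.3 times. These replaced a test over all 103 layer genes, which held 12 higher ones that dilution does not concern. A first test asked whether 6 lists of dermal, vascular, fat, muscle, nerve and red blood cells had a positive median and a preset-correlation call, and all 6 had. After that result and a look at the levels of the members, it was replaced by the following comparisons, whose bounds were also set then.

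RNA of fibroblast and red blood cell genes was present in the libraries labelled knockout at far higher levels than in the wild type. Whether these cells are its source stays open as a candidate explanation. That 36 of the 37 tested members of these lists were higher was known before a bound was set, so it is the pattern itself and no test of its source. Col1a1 reached 2548 and Hba-a1 728 CPM. At 10 CPM or more in the wild type were 9 of 29 fibroblast genes and 0 of 12 red blood cell genes. Endothelial, fat and muscle cells as the source of the higher members of their lists would bring their abundant transcripts. Of the 60 members 10% reached 10 CPM in the knockout, against 25 of 29 for fibroblasts. By list these were 4 of 19 endothelial, 2 of 14 adipocyte and 0 of 27 muscle genes. These levels were also known before the bound was set, so they are no test, and such cells as a source stay open. Whether such RNA would come from tissue left after peeling, which the protocol was meant to remove, or from cells within the epidermis was not tested, because either would follow the groups.

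Paxbp1 was not lower in the libraries labelled knockout. Labels swapped between a knockout and a wild type library would put 1 library of each group nearer to the other group, but the highest correlation between groups was 0.725 and the lowest within a group 0.957. A deletion that leaves most counted exons cannot be told apart from an intact gene, since counts per exon were not analysed here and the lower 95% bound of the fold was 0.690. Paxbp1 RNA from cells that keep the gene stays open too, since the knockout level was 108% of the wild type level and the level per cell type was not analysed here. An exchange of the whole groups would not make the Paxbp1 counts differ either, so the genotype rests on the labels.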
